A study of Mus musculus with 6 samples.

How the data were processed

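RNA from 6 samples of sorted mouse splenic NK cells, 3 Ly49C/I+ and 3 Ly49G2+, was measured on an Affymetrix gene array. Per the labels, cells were grown for 7 days with 1000 IU of interleukin-2 before sorting, 100 ng of RNA was amplified and biotin-labelled, and RNA integrity numbers were above 9. Groups and replicate numbers were taken from the sample titles. Per the submitters' processing notes, Partek and RMA were used, and their versions and settings were not given in the sources used here. RMA is robust multi-array averaging, which corrects background, quantile-normalizes and summarizes probes. The labels give the strain as C57BL/6 in the protocol and C57BL/5 in the strain field. No column of per-sample values was left unused.

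The authors deposited a value table with log2 values of exon-level probe sets on each array. They also deposited a table of 35556 transcript clusters with a group mean on the log2 scale, a p-value and a ratio per cluster. Per the file headers, that p-value comes from an ANOVA with sample set as the only factor, and the p-value recomputed from the deposited sums of squares with 4 residual degrees of freedom lay within 1 percent of it in 100% of clusters. Per the file headers, the ratio is Ly49C/I+ over Ly49G2+, and the deposited fold column holds the same ratio with its inverse written as a negative number. Gene symbols came from this table, for 24692 clusters, and 10864 clusters had none.

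Probe sets were joined to clusters by ID number, since a cluster's probe sets follow its ID in an unbroken run. The join placed 241383 probe sets and left out 193, with a median of 7 probe sets per named cluster. It was checked against the authors' deposited means. Across clusters, which are not independent replicates, run means and deposited means correlated at r = 0.987 for Ly49C/I+ and 0.986 for Ly49G2+, and group differences at 0.947. With runs shifted by 1 cluster these fell to 0.247 for Ly49C/I+ means and 0.112 for differences. All 112 named clusters with a deposited fold above 1.5 had the same direction after the join. Symbols were updated through RefSeq accessions of assembly GRCm38.p6, where 21020 accessions matched and 1926 clusters received a newer symbol. The files name no genome build, so no coordinates are given. Log2 values were averaged over the probe sets of each cluster and over clusters of 1 gene (1901 genes had more than 1), which gave 21442 genes. The design had been fixed for values per gene, and the averaging was the step it prescribed for exon-level rows.

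Differences are Ly49C/I+ minus Ly49G2+. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend, no filter on signal), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Python 3.11.15, pandas 2.3.3 and numpy 2.4.6 were used for joins, and matplotlib 3.10.9 for figures. For the sorting receptors an exact permutation test was run as well. Lists were tested with camera at a preset correlation of 0.01, adjusted over 20 lists, with camera at an estimated correlation and fry beside it. Camera compares the members with the other genes, whereas fry tests the members alone. A list can therefore pass fry without differing more than other genes. Of the lists that passed camera at the preset correlation, 5 in all, 0 passed with an estimated correlation. The Ly49 list, 1 of these 5, holds genes of the sorting receptors, so its direction follows in part from the sort. Lists and tests were fixed before the data were examined.

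Genes named in the text follow a rule fixed at the same time. They are Klra7, Klra3 and Klra9, the 10 genes with the largest log2 difference in each direction among those with adjusted p under 0.05 and no overlap of the subsets, with clone and locus identifiers counted but not named, and from each list the 3 members of lowest p with any further passing members, up to 8 per list. A few others are named as members that did not pass or to describe a group, and were chosen after their values were seen. Klra7 was not analysed here, and some genes that the rule would name are not reported here.

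The test was tried on simulated data with the means and spreads of the 21442 genes of this comparison, 200 of them changed, in 10 runs. It recovered 41.5% of changes of 1.2-fold, 92.8% of 1.5-fold and 99.5% of 2-fold, and 3.88% of calls were false. The simulation changed far fewer genes than the 2118 called in the data and drew the noise of each gene independently. These shares therefore describe the simulated setting and cannot be carried over to the real calls. Arrays give no read depth, and 3 arrays per group limit the precision.

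Alternatives fixed in advance were a variance trend with robust moderation, quantile normalization again, median centring, filters at the median and at the 25th percentile of signal, the highest row per gene, array weights, the replicate number as a block, each array left out, a test without moderation, the authors' deposited p-values, and other list tests. Chosen after seeing the data were the median over probe sets and a moderated test on the deposited means. Clusters with no gene symbol were left out of the gene tests.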

Results

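Gene expression was measured by microarray in natural killer (NK) cells from the spleens of C57BL/6 mice. NK cells carry Ly49 receptors, a family of surface lectins of which several inhibit killing on binding MHC class I. The spleen cells were depleted of T cells through Thy1.2, grown in interleukin-2 and sorted as CD3-negative, CD122-positive cells. The sort kept cells with Ly49C or Ly49I and no Ly49G2 (Ly49C/I+) apart from cells with Ly49G2 and neither of the others (Ly49G2+). Ly49C and Ly49I bind class I molecules of this strain, so that Ly49C/I+ cells are commonly called licensed and Ly49G2+ cells unlicensed. There were 3 arrays for each subset, and their number limits the precision of every value below. The labels do not say whether the samples came from separate mice or cultures, so the p-values measure only the spread between these samples, which may be technical. Median signals of the 6 arrays lay between 7.73 and 7.75 on the log2 scale over all exon-level probe sets.

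The comparison asked which genes differ between the subsets. Ly49C/I+ cells had more Klra9, the gene of Ly49I (3.94-fold), and more mRNA of most cell cycle genes, such as Birc5 (1.63-fold) and Prc1 (1.44-fold). Ly49G2+ cells had more Cd3e (4.69-fold), Cd3d (3.41-fold) and Cd3g (1.99-fold), which encode chains of the T cell receptor complex. Most other differences were small, with a median of 1.21-fold among the genes that passed. Transcripts of the main killing proteins perforin (Prf1) and granzyme B (Gzmb) differed by log2 values of -0.04 ± 0.042 and 0.07 ± 0.056 (SE), with adjusted p of 0.607 and 0.528.

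Of 21442 genes tested with limma, 2118 (9.88%) had an adjusted p under 0.05. They comprised 1321 genes higher in Ly49C/I+ cells and 797 higher in Ly49G2+ cells, and 106 of the 2118 also differed by at least 1.5-fold, 77 of them higher in Ly49C/I+ cells and 29 higher in Ly49G2+ cells. This split depended on the setting. At 1.5-fold it was 58 and 33 without Ly49G2+ replicate 2, 59 and 32 with array weights, and 63 and 31 after quantile normalization again. That normalization gave 1277 and 1024 genes without the fold threshold. The threshold of at least 1.5-fold with an unadjusted p under 0.05, closer to the submitters' own fold criterion, gave 107 genes. The values of the subsets did not overlap in 27.8% of genes, where chance gives 10%. The count was 1351 without Ly49C/I+ replicate 2, 1403 without Ly49C/I+ replicate 3, 898 without variance moderation, 691 with the median of a gene's probe sets in place of their average, and 1118 with the p-values of the authors' deposited table. Without Ly49C/I+ replicates 1, 2 and 3, genes higher in Ly49G2+ cells numbered 496, 492 and 410. Without Ly49G2+ replicates 1, 2 and 3 they numbered 491, 765 and 507. Those higher in Ly49C/I+ cells numbered 859 to 1112 with 1 array left out, the fewest without Ly49C/I+ replicate 2. In a principal component analysis, Ly49G2+ replicate 2 lay apart from the other Ly49G2+ arrays. Its first 2 components were 14.25 and 9.11, against 8.02 and -5.92 for replicate 1 and 7.44 and -7.1 for replicate 3. Of 117 passing genes picked by the naming rule, 48 passed in all their alternative analyses, 12 failed in most of them, and 30 had a log2 difference that moved by over 1.5 times or turned in at least 1.

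The Ly49 genes, which check the sort, lie on chromosome 6 where the authors' deposited table gives a position, which it does not for Klra5 and Klra11. Klra9 was at 11.65 ± 0.16 (log2 signal, SD, n = 3) in Ly49C/I+ cells and 9.67 ± 0.19 in Ly49G2+ cells, a log2 difference of 1.98 ± 0.10 (SE). Klra3, the gene of Ly49C, was 1.80-fold higher in Ly49C/I+ cells, with a log2 difference of 0.85 ± 0.069 (SE), and 1.27 with the median of its probe sets. The limma adjusted p was 1.3e-05 for Klra9 and 0.000137 for Klra3. An exact two-sided permutation test gave p = 0.1 for each, the smallest that 3 against 3 arrays allow. Klra10 (4.13-fold), Klra11 (4.82-fold, with 1 probe set behind it) and Klra5 (1.39-fold) were also higher in Ly49C/I+ cells. Klra2 was 1.28-fold higher in Ly49G2+ cells, a call that failed in 11 of 17 alternative analyses. The authors' deposited table gives Klra10 a ratio of 2.01, so its fold rests on how probe sets are combined. Klra6, Klra8 and Klra17 did not pass, with log2 differences of 0.20, 0.37 and -0.01. Klra11 is not a member of the Ly49 list. Of 9 measured genes of the Ly49 list, 4 were higher in Ly49C/I+ and 2 in Ly49G2+ cells, and adjusted over the list alone 6 and 2 (4 to 6 and 1 to 2 over all genes with 1 array left out). The list as a whole was higher in Ly49C/I+ cells by camera (adjusted p = 0.00422), and adjusted p = 0.617 with an estimated correlation. This direction is no independent result. The list holds Klra9 and Klra3, whose products were used for the sort, while Klra7 was not analysed. Some Ly49 genes are near-identical copies, so that such members cannot be fully separated. On all arrays 1 probe set of Klra9 and 1 of Klra10 held identical values. Klra7, the gene of Ly49G2, was not analysed here. The source label of Ly49G2+ replicate 1 names the other subset, whereas its title does not, and its Klra9 and Klra3 values (9.78 and 10.02) lay with those of the other Ly49G2+ arrays.

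**Figure D1:**
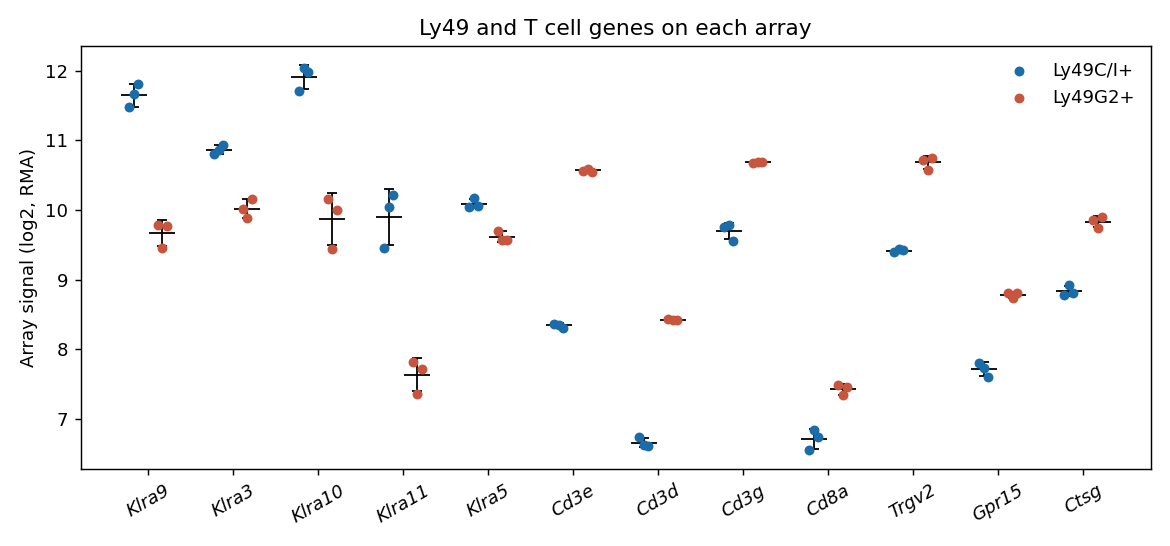
Signal (log2, RMA) of 12 genes on each array, with blue points for Ly49C/I+, red points for Ly49G2+, and black marks for the mean ± SD of 3 arrays. Klra9 lies near 11.65 in Ly49C/I+ and 9.67 in Ly49G2+ cells, while Cd3e lies at 8.34 and 10.57.

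The array row named Klra1 averaged 1.64-fold higher in Ly49G2+ cells (log2 difference -0.72 ± 0.064, SE), but its 41 probe sets did not move together. In a run of 9 neighbouring probe sets every Ly49G2+ array lay above every Ly49C/I+ array. The run was picked as the longest with large differences toward Ly49G2+ cells, so its sizes and separation follow in part from that choice. In 7 of the 9 the log2 difference toward Ly49G2+ cells was 2.44 to 4.91. The other 2 lay at 4.72 and 4.51 in Ly49C/I+ cells, below the arrays' lower quartile of 5.82, so no size is given for them. The other 32 probe sets of Klra1 averaged 8.33 in Ly49C/I+ and 8.13 in Ly49G2+ cells, and they went both ways. Of these, 4 lay higher on every Ly49G2+ array. More lay higher on every Ly49C/I+ array, namely those at positions 4, 6, 7, 8, 9, 25, 26, 27, 39 and 40 by ID. Among the 32 the difference was largest at position 39, with 8.44 in Ly49C/I+ and 6.33 in Ly49G2+ cells. The authors' deposited table gives a ratio of 0.920 for Klra1 with p = 0.117, so the call for this gene rests on how its probe sets are combined. Over 18 alternative analyses its log2 difference ran from -1.95 to -0.12. Probe sequences were not used here, so the signal of the 9 cannot be assigned to Klra1 rather than another Ly49 gene such as Klra7, and the same holds for the Klra1 call counted in the Ly49 list.

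**Figure D2:**
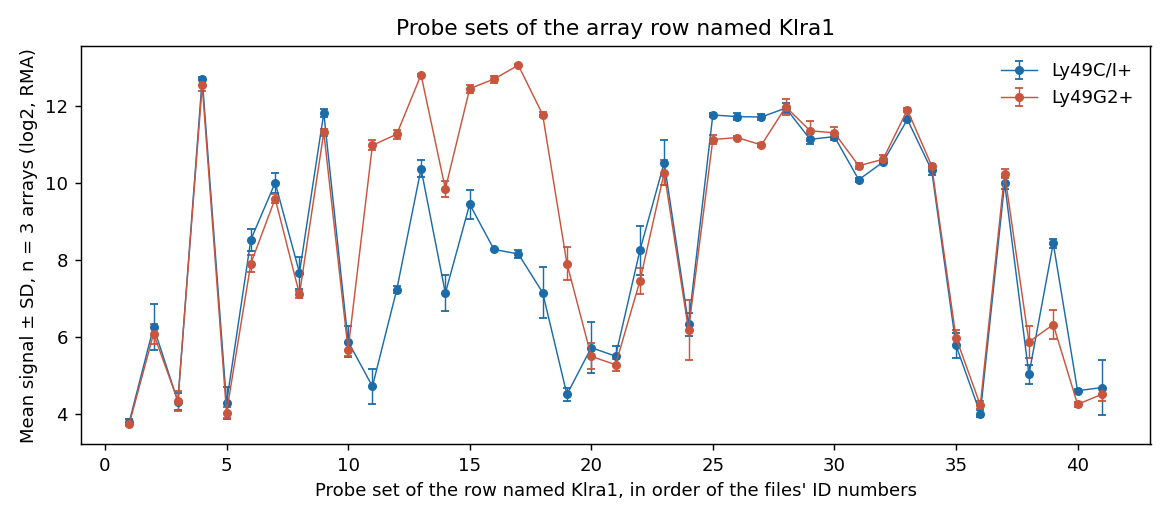
Mean signal ± SD (log2, RMA, n = 3 arrays) of each of the 41 probe sets of the row named Klra1, in order of ID number, for Ly49C/I+ (blue) and Ly49G2+ (red). Probe sets 11 to 19 form the run of 9 that lies higher on every Ly49G2+ array, and probe sets 11 and 19 lie below the arrays' lower quartile of 5.82 in Ly49C/I+ cells.

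Apart from Ly49 genes, 4 of 15 measured T cell markers were higher in Ly49G2+ cells and 0 in Ly49C/I+ cells, with the same counts adjusted over the list alone and 4 and 1 at an unadjusted limma p under 0.05. Cd3e was at 10.57 ± 0.021 (SD, n = 3) in Ly49G2+ and 8.34 ± 0.030 in Ly49C/I+ cells, a log2 difference of -2.23 ± 0.042 (SE, limma adjusted p = 6.05e-09). Cd3d and Cd3g followed with -1.77 ± 0.047 and -0.99 ± 0.059, and Cd8a, a chain of the CD8 co-receptor, with -0.72 ± 0.073. The remaining 11 markers, among them Cd4, Cd5, Cd6, Cd8b1, Thy1 and Cd28, did not pass, with log2 differences between -0.12 and 0.10. The list also held the T cell receptor genes Trac, Trbc1, Tcrg-C1 and Tcrg-V4. These matched no gene tested and are not among the 15. The list passed camera (adjusted p = 0.000648), and had adjusted p = 0.545 with an estimated correlation. T cell receptor segments Trgv2 (2.41-fold) and Trav12-2, which lay below the arrays' lower quartile in Ly49C/I+ cells (5.66), were higher in Ly49G2+ cells as well. The log2 difference of Trgv2 was -0.77 in the authors' deposited table. Trgv2 was named by its size and Trav12-2 after its value was seen.

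Further genes with the largest differences toward Ly49G2+ cells were Gpr15, a homing receptor of lymphocytes (2.10-fold), Klk1b11, a kallikrein (2.02-fold), and Ctsg, the granule protease cathepsin G (1.99-fold). Dsc2, a desmosomal cadherin, was 1.91-fold higher in Ly49G2+ cells, and so were Snora44 (1.73-fold) and Sh2d1b2, an adaptor of SLAM family receptors (1.70-fold). Toward Ly49C/I+ cells, small non-coding RNAs followed the Ly49 genes. Scarna13 was 2.49-fold, Snord37 2.07-fold, Snora75 1.89-fold and Snord14a 1.84-fold higher there, with 1 probe set behind each. Phtf1os, which lay below the arrays' lower quartile in Ly49G2+ cells (5.51), Mir142, a microRNA of blood cells (1.87-fold), and Pnet-ps (1.84-fold) completed the 10 named, and 2 clone or locus identifiers of like size were not named. Array rows with no gene name moved the same way in part, since 6615 of them had a median log2 difference of 0.12 toward Ly49C/I+ cells, and what these rows probe is not given in the sources used here.

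Cell cycle genes were the list with the most members on 1 side. Of 46 measured, 40 were higher in Ly49C/I+ cells, 0 in Ly49G2+ cells and 6 did not pass, and 42 and 0 did so adjusted over the list alone or at an unadjusted limma p under 0.05. Birc5 (survivin, 1.63-fold), Cdk2 (log2 difference 0.68), Cdkn2c (1.52-fold), an inhibitor of Cdk4 and Cdk6, and Prc1 (1.44-fold), which organises the spindle midzone, were among them. Aurkb, Bub1, Ccnb1 and Kif20a, all of mitosis, were 1.35-fold, 1.41-fold, 1.37-fold and 1.32-fold higher. The median member differed by 0.35 on the log2 scale, and camera gave adjusted p = 7.63e-35. With an estimated correlation, adjusted p = 0.0542 for this list. The number higher in Ly49C/I+ cells was 24 with the median over probe sets, 27 without variance moderation, and 32 with the p-values of the authors' deposited table, where 1 (Cdkn1a, an inhibitor of cyclin-dependent kinases) was higher in Ly49G2+ cells.

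**Figure D3:**
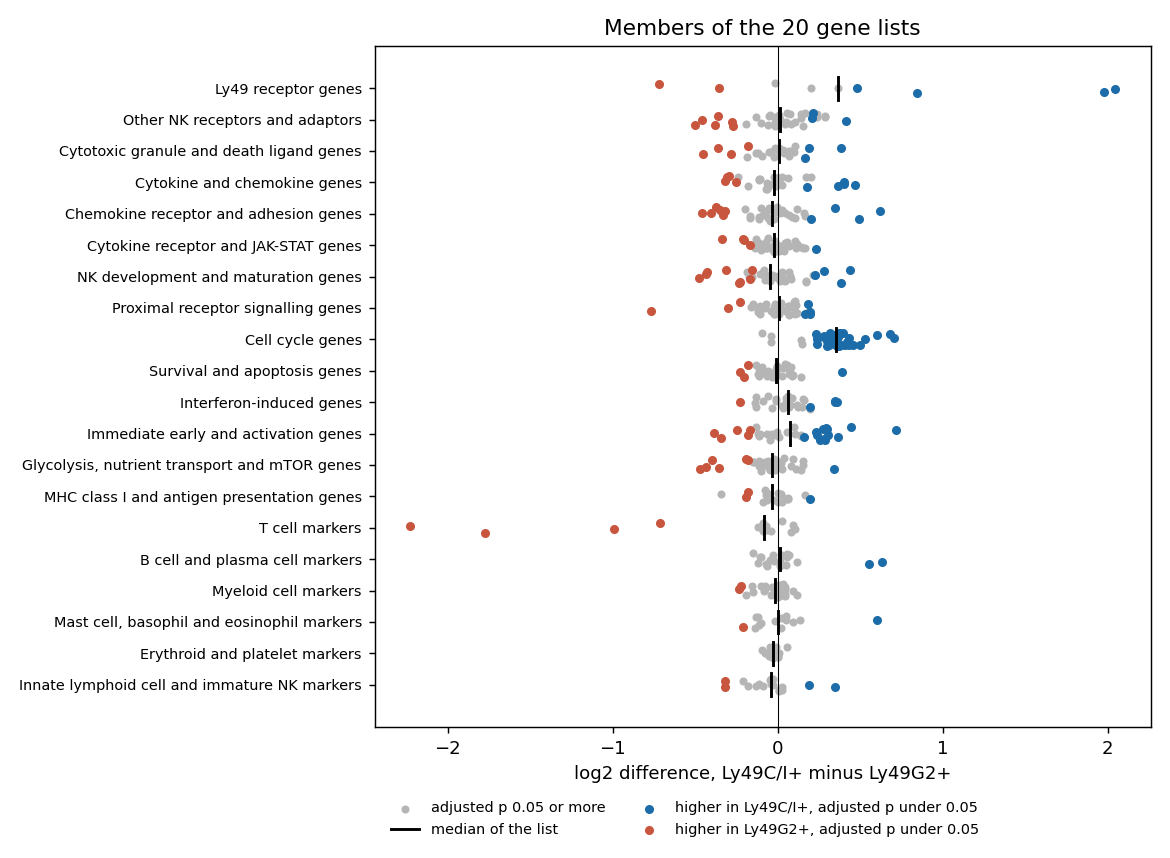
Log2 difference (Ly49C/I+ minus Ly49G2+) of each measured member of the 20 lists, coloured where adjusted p was under 0.05 (blue higher in Ly49C/I+, red higher in Ly49G2+) and grey otherwise, with black bars at list medians. The 40 called cell cycle genes lie right of 0, and 4 T cell markers lie left of it.

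Of 34 immediate early and activation genes, 13 were higher in Ly49C/I+ and 5 in Ly49G2+ cells, and 15 and 7 adjusted over the list alone, while with 1 array left out the counts were 11 to 12 and 1 to 3. Fosb (1.64-fold) and Fos (1.36-fold), parts of the AP-1 transcription factor, were higher in Ly49C/I+ cells with Rgs2 (1.29-fold), Tnfaip3 (1.24-fold), Dusp1 (1.23-fold), Myc (1.23-fold) and Rgs1 (1.22-fold). Rgs16 was 1.31-fold higher in Ly49G2+ cells. With the median over probe sets Dusp1, Myc and Rgs1 did not pass (limma adjusted p = 0.0525, 0.0842 and 0.302). Among 30 interferon-induced genes, Xaf1 (1.29-fold), Ifit2 (1.27-fold), Oas1a (1.27-fold) and Oasl1 (1.15-fold, a call that failed in 13 of 18 alternatives) were higher in Ly49C/I+ cells, and Mx1 (1.17-fold) in Ly49G2+ cells, with 5 and 1 adjusted over the list alone. With 1 array left out, 2 to 4 and 0 to 1 of the interferon-induced genes passed. None of the interferon-induced genes named here passed with the median over probe sets or without variance moderation. For Oas1a the median gave a log2 difference of 0.14 (limma adjusted p = 0.462). Both lists passed camera (adjusted p = 0.0251 and 0.0386), and had adjusted p = 0.545 and 0.571 with an estimated correlation. The interferon list failed in 11 of 18 alternative camera analyses (adjusted p 0.0184 to 0.571) and the immediate early list in 7 of 18 (adjusted p 0.0110 to 0.545).

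Secreted factors went both ways, with 5 of 31 cytokine and chemokine genes higher in Ly49C/I+ and 4 in Ly49G2+ cells, and 7 and 6 adjusted over the list alone. Ly49C/I+ cells had more of the chemokines Ccl4 (1.38-fold), Ccl5 (1.32-fold), Ccl9 (1.32-fold) and Cxcl10 (1.29-fold), but with the median over probe sets the log2 difference of Ccl4 went from 0.47 to 0.20 and did not pass (adjusted p = 0.124, the highest of its alternatives). Ly49G2+ cells had more Ltb (1.25-fold), Csf2 (1.24-fold), Tnfsf11 (1.23-fold) and Areg (1.19-fold), which encode lymphotoxin beta, GM-CSF, RANK ligand and amphiregulin. Of 18 alternative analyses, Areg failed in 7, Ltb in 3, Csf2 in 2 and Tnfsf11 in 1. Ccl4 failed in 1, and Ccl5, Ccl9 and Cxcl10 in 0. The log2 difference of Ifng was -0.11 ± 0.046 (SE), with adjusted p = 0.203. The list did not pass camera (adjusted p = 0.741), and its median of -0.02 and its test lay toward Ly49G2+ cells while its mean was just above 0.

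Of 27 cytotoxic granule and death ligand genes, 3 were higher in Ly49C/I+ and 4 in Ly49G2+ cells, and 3 and 5 adjusted over the list alone, while with 1 array left out the counts were 0 to 1 and 3 to 4. The granzyme genes Gzmf (1.37-fold), Gzmg (1.28-fold) and Gzme (1.22-fold), which neighbour each other in the genome, and Stx11 (1.13-fold) were higher in Ly49G2+ cells. Tnfsf10 (1.14-fold), Srgn (1.31-fold) and Gzma (1.12-fold) were higher in Ly49C/I+ cells, but Srgn failed in 10 and Gzma in 11 of 18 alternative analyses. Stx11 failed in 9 and Tnfsf10 in 7 of 18. The difference of Srgn was 0.01 on the log2 scale with the median over its probe sets (adjusted p = 0.961, the highest of its alternatives), and the authors' deposited table gives Srgn a ratio of 1.01. Of 36 other NK receptors and adaptors, 3 were higher in Ly49C/I+ and 6 in Ly49G2+ cells, and 8 and 8 adjusted over the list alone, while with 1 array left out the counts were 1 to 3 and 4 to 6. Klrc2 (NKG2C, 1.33-fold) and Klrk1 (NKG2D, 1.16-fold) were higher in Ly49C/I+ cells. Ceacam1 (1.42-fold), Havcr2 (TIM-3, 1.37-fold), Pilrb1 (1.30-fold), Klrb1a (1.28-fold), Crtam (1.21-fold) and Klri1 (1.21-fold) were higher in Ly49G2+ cells. Klrk1 failed in 9 and Klrc2 in 3 of 18 alternative analyses. Toward Ly49G2+ cells, Havcr2 failed in 6, Klrb1a in 5 and Klri1 in 4, and Ceacam1, Pilrb1 and Crtam in 1 each. Neither list passed camera (adjusted p = 0.665 and 0.685), and the cytotoxic list had a median above 0 (0.0070) with a mean of -0.02 and a test toward Ly49G2+ cells.

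Among 35 chemokine receptor and adhesion genes, 4 were higher in Ly49C/I+ and 6 in Ly49G2+ cells, and 6 and 9 adjusted over the list alone. Cxcr6, a receptor of liver NK cells and resident lymphocytes (1.54-fold), and Itgax (CD11c, 1.41-fold) were higher in Ly49C/I+ cells. Itgae (CD103, 1.38-fold), Cxcr3 (1.33-fold), Ly6c1 (1.30-fold), Ly6c2 (1.28-fold), Itgb3 (1.25-fold) and S1pr1, which lay below the arrays' lower quartile in Ly49C/I+ cells (5.57), were higher in Ly49G2+ cells. Of 43 NK development and maturation genes, 4 were higher in Ly49C/I+ and 8 in Ly49G2+ cells, and 7 and 10 adjusted over the list alone, while with 1 array left out the counts were 3 to 4 and 5 to 8. Zbtb16 (PLZF, 1.35-fold), Tox (1.30-fold) and Runx1 (1.22-fold) were higher in Ly49C/I+ cells, whereas Irf4 (1.39-fold), Ikzf2 (Helios, 1.35-fold), Zbtb32 (1.34-fold), Cd27 (1.24-fold) and Irf8 (1.17-fold) were higher in Ly49G2+ cells. Eomes and Tbx21, the transcription factors central to NK cells, had log2 differences of -0.05 ± 0.049 and 0.08 ± 0.045 (SE) and did not pass. Neither list passed camera (adjusted p = 0.463 and 0.410). The chemokine receptor and adhesion list passed fry, which does not compare members with other genes (adjusted p = 0.0040).

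Glycolysis, nutrient transport and mTOR genes comprised 36, of which 1 was higher in Ly49C/I+ and 6 in Ly49G2+ cells, and 1 and 7 adjusted over the list alone. Slc7a11 (1.38-fold) and Slc7a5 (1.13-fold), amino acid transporters, Ddit4 (1.35-fold) and Sesn2 (1.32-fold), inhibitors of mTORC1, Hif1a (1.28-fold) and the lactate transporter Slc16a3 (1.14-fold, failing in 10 of 18 alternatives) were higher in Ly49G2+ cells. Sesn1 was 1.27-fold higher in Ly49C/I+ cells. The list did not pass camera (adjusted p = 0.0689), but passed in 8 of 18 alternative camera analyses (adjusted p 0.0118 to 0.545). It passed fry as well (adjusted p = 0.0069).

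Of 39 cytokine receptor and JAK-STAT genes, Tgfbr1 (1.18-fold) was higher in Ly49C/I+ cells and Il6st (1.26-fold), Il1rl1, Kit (1.15-fold) and Stat5b (1.12-fold) in Ly49G2+ cells, and 3 and 4 passed adjusted over the list alone. Il1rl1, which lay below the arrays' lower quartile in both subsets (5.60 and 5.81), failed in 12 of 16 alternatives and Stat5b in 11 of 18. Of 43 proximal signalling genes, Ptpn6 (1.15-fold), Sh2d1b1 (1.14-fold) and Vav1 (1.12-fold) were among those higher in Ly49C/I+ cells, and Sh2d1b1 and Vav1 each failed in 10 of 18 alternatives. Sh2d1b2, Cblb (1.23-fold) and Ubash3b (1.17-fold) were higher in Ly49G2+ cells, and 5 and 4 of the proximal signalling genes passed adjusted over the list alone. Of 30 survival genes, Fas (1.17-fold), Tnfrsf10b (1.15-fold) and Bcl2l1 (1.13-fold) were higher in Ly49G2+ cells, and 3 passed in that direction adjusted over the list alone, but Tnfrsf10b failed in 10 of 18 alternatives and Fas turned to 0.15 on the log2 scale with the median over probe sets. Of 22 MHC class I and antigen presentation genes, Psmb10 (1.15-fold) was higher in Ly49C/I+ and Tap2 (1.14-fold, failing in 10 of 18 alternatives) and H2-M3 (1.13-fold) in Ly49G2+ cells, and 1 and 3 passed adjusted over the list alone. None of these 4 lists passed camera (adjusted p = 0.577, 0.638, 0.638 and 0.577), and the proximal signalling list had a mean of -0.0030 with a median and a test toward Ly49C/I+ cells. With 1 array left out, the proximal signalling list had 0 or 1 calls toward Ly49C/I+ cells by limma and the MHC class I list 0 or 1 in each direction, and toward Ly49G2+ cells the cytokine receptor list had 1 or 2 and the survival list 0 to 2.

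Markers of other cells that a spleen culture could hold were mostly alike. Of 21 B cell and plasma cell markers, Bank1 (1.47-fold) and Ighm, which lay below the arrays' lower quartile in both subsets (5.23 and 4.60), were higher in Ly49C/I+ cells, and Cd79b did not pass (log2 difference -0.15 ± 0.057, SE). Of 30 myeloid markers, Cd14 (1.16-fold, failing in 9 of 17 alternatives) and Ly6g, which also lay below that quartile (5.20 and 5.43), were higher in Ly49G2+ cells, and C1qb did not pass (log2 difference -0.16 ± 0.050, SE). Of 14 mast cell, basophil and eosinophil markers, Cpa3 (1.52-fold) was higher in Ly49C/I+ and Mcpt8 (1.16-fold) in Ly49G2+ cells, and Tpsab1 did not pass (log2 difference -0.12 ± 0.046, SE). None of 12 erythroid and platelet markers passed by limma, with 0 at an adjusted and 0 at an unadjusted p under 0.05, Epor, Slc4a1 and Pf4 coming nearest at log2 differences of -0.10, -0.07 and -0.05. Of 18 innate lymphoid and immature NK markers, Cd200r1 (1.27-fold) and Tnfsf10 were higher in Ly49C/I+ cells, and Itgb3 and Ltb in Ly49G2+ cells. Counts adjusted over the list alone were the same for these 5 lists, and none passed camera (adjusted p = 0.638, 0.577, 0.741, 0.638 and 0.332). The innate lymphoid list passed fry (adjusted p = 0.0362). The mast cell, basophil and eosinophil list had a mean of 0.010 with a test toward Ly49G2+ cells. No Ly49C/I+ call was made in the myeloid list, with 0 at an unadjusted limma p as well, and no Ly49G2+ call in the B cell list, with 1. With 1 array left out, the myeloid list had 0 to 2 and the mast cell list 0 to 1 calls toward Ly49G2+ cells, and the innate lymphoid list 0 to 2 toward Ly49C/I+ cells.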

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

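The tests in this part were all chosen after the result was seen. Array rows with no gene name took part in no comparison above. Of these, 6615 have ID numbers before that of the first named row, each with 1 probe set. Fitted with limma, 638 of them were higher in Ly49C/I+ cells and 25 in Ly49G2+ cells at an adjusted p under 0.05, and 419 and 1 of these differed by at least 1.5-fold. Their median on the arrays was 6.10 to 6.19 in Ly49C/I+ and 5.83 to 5.88 in Ly49G2+ samples. Among the other 4249 rows with no gene name, 83 and 25 passed, with a median log2 difference of 0.0033.

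A general background shift of dim rows is argued against. At signals between 5 and 8, the early rows had a median log2 difference of 0.24, and 2061 named rows with 1 probe set had -0.007, a gap of 0.247. The quartiles of those named rows were -0.057 and 0.050. More unspliced RNA or genomic DNA in the Ly49C/I+ samples may account for the median shift of 0.117, if these rows lie outside exons, but what they probe is not given in the sources used here, so this stays open. That these rows are control features of the array, and a difference between the subsets themselves, stay open too and were not tested.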

How the results depend on the processing

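The median over probe sets and the moderated test on the deposited means were chosen after seeing the data. The count of 2118 genes was 898 without moderation, 1118 with the authors' deposited p-values and 691 with the median over probe sets, and it ran from 1351 to 1877 when 1 array was left out (1351 without Ly49C/I+ replicate 2, 1403 without Ly49C/I+ replicate 3). Leaving out an array gives fewer samples, and a test without moderation has fewer degrees of freedom. The causes of these changes in count were not tested. The count by fold and unadjusted p was 184 with the median over probe sets, and the count at 1.5-fold with adjusted p stayed between 77 and 149 over all alternatives. Klra9 and Klra3 kept their direction and passed in all 18 alternatives (log2 differences 1.62 to 2.12 and 0.64 to 1.27). Of the 5 lists that passed, 0 did with an estimated correlation (1 list had an unadjusted p under 0.05), while 7 of the 20 lists passed fry. These were the Ly49, cell cycle, T cell, immediate early, chemokine receptor, glycolysis and innate lymphoid lists. The interferon list did not pass fry (adjusted p = 0.0859). The count of lists was 3 with the filter at the 25th percentile, 3 with the median over probe sets, and 3 without Klra and dim genes, a setting that empties the Ly49 list. List directions turned in 17 of 379 list tests, in 0 of which either test passed. With the median over probe sets Fas turned to 0.15 and Cd79b to 0.16, and Slc4a1 turned to 0.018 in both analyses of the deposited means, and the cause was not tested. With the replicate number as a block 1476 genes passed. The labels do not say that equal numbers mark a shared animal, so a main fit without pairs was fixed in advance. Same-numbered samples did not deviate together (r = -0.076, -0.186 and -0.046 across genes, 0 of the 6 samples closest to their own number). With 3 arrays per group, these values cannot decide whether the samples were paired. Of 117 genes picked by the naming rule that passed, between 16 and 29 no longer did with 1 array left out, 45 without moderation, 43 with the authors' deposited p-values and 57 with the median over probe sets. The 12 that failed in most of their alternatives were Oasl1, Il1rl1, Gzma, Klra2, Stat5b, Sh2d1b1, Slc16a3, Srgn, Tap2, Tnfrsf10b, Vav1 and Cd14. Calls summed over the 20 lists were 156, and 86 without moderation, 112 with the authors' deposited p-values and 64 with the median over probe sets, which moved the count of 17 lists by over 1.5 times. With 1 array left out they were 115 to 139, which moved 3 to 9 lists that far (9 without Ly49C/I+ replicate 2 or 3), and with the replicate number as a block 120, which moved 8. Dim genes near the array's background limit what small differences can show, and Phtf1os, S1pr1, Il1rl1, Ighm and Ly6g lay below the arrays' lower quartile of 5.82 in at least 1 subset, as did Trav12-2 (5.66 in Ly49C/I+ cells).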

Other observations

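The groups in this paragraph were formed after their values were seen. Of 69 small nucleolar and Cajal body RNAs, which guide chemical modification of other RNAs, 31 were higher in Ly49C/I+ cells and 3 in Ly49G2+ cells (Snora44, Snord35a and Snord33), with 1 probe set behind 59 of them. Snord16a, Snora23 and Snora28 had log2 differences of 0.81, 0.84 and 0.79. Of 60 histone genes of the replication-dependent clusters, 29 were higher in Ly49C/I+ and 0 in Ly49G2+ cells by limma (0 also at an unadjusted p), with a median log2 difference of 0.22. They too rested in part on few probe sets, with 1 behind 36 of them. The correlation estimated among the histone genes was 0.455, so their calls are not independent of each other. Array rows before the first named row also moved toward Ly49C/I+ cells (median log2 difference 0.117), and whether this is linked to these groups was not tested. Among 327 microRNA genes 21 and 0 passed (9 higher in Ly49G2+ cells at an unadjusted p), and among 86 ribosomal protein genes 1 and 1. Camera over these 4 groups gave adjusted p = 1.71e-12, 3.43e-27, 0.0308 and 0.801, and adjusted p = 0.126, 0.126, 0.587 and 0.959 with an estimated correlation.

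The tests of other markers, of receptor segments and of left-out arrays below were chosen after the result was seen. Cd3e, Cd3d, Cd3g and Cd8a were higher in Ly49G2+ cells although the sort excluded CD3-positive cells and Thy1.2-bearing cells had been depleted. A few faulty probe sets are argued against, since in 26 of 28 probe sets of these genes every Ly49G2+ array lay above every Ly49C/I+ array. T cells that carry the other measured markers as strongly as Cd8a are argued against too. The median of the other 11 rose by 0.062 in Ly49G2+ cells (SD 0.082), where Cd8a rose by 0.72. The listed receptor genes Trac, Trbc1, Tcrg-C1 and Tcrg-V4 matched no gene tested and are not among the 11. Most of these 11 lie low on the array, while Thy1 and Cd28 lie high in Ly49C/I+ cells too (12.45 and 10.89), so a smaller share of T cells is not excluded by them. T cells poor in these markers, or NK cells with more of these transcripts, cannot be told apart in sorted pools, and may both bring the 4 of 6 T cell receptor segments that were higher in Ly49G2+ cells (Trgv2, Trav12-2, Trav7-4 and Trav9d-3).

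For the cell cycle list, a shift that depends on signal level is argued against. The list's median of 0.35 lay at percentile 100 of 10000 random lists matched on mean level, the highest of which was 0.077. A single deviating array is argued against as well, with 37 of 46 members still higher in Ly49C/I+ cells in the run that kept fewest, though 24 with the median over probe sets. A larger share of dividing cells among cultured Ly49C/I+ cells is a hypothesis that may explain the pattern and was not tested, and growth differing between cultures stays open, since the labels do not say how cultures map to samples.

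Of the 10 splits of the 6 samples into 3 and 3, 1, the real one, gave 2118 genes, and the highest of the others gave 0 by limma (4925 against at most 891 at an unadjusted p). With 10 splits no share under 0.05 can be reached.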
